A study of Pimephales promelas with 16 samples.

How the data were processed

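The series holds 16 one-colour microarrays of total RNA from ovary explants of female fathead minnow (Pimephales promelas), 4 arrays in each of 4 groups. Per the labels, explants were incubated for 12 h, and the 3 treated groups received DHT, flutamide or LIN at 1e-06 M. The labels call the remaining group control and do not say whether it received a carrier. Per the labels, RNA was extracted with TRIzol, extracts of lower integrity were cleaned on a column, and RNA was labelled with Cy3 by Agilent's one-colour protocol. Which extracts were cleaned is not given in the sources used here. The labels do not say whether replicates came from separate fish, so the p-values measure the spread between these samples, part of which may be technical.

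Each array's file is scanner output of Agilent Feature Extraction 10.7.1.1, per the file headers. It gives for each spot an intensity on a linear scale, background-subtracted and detrended within the array per the file headers, and not scaled between arrays. It also gives the median intensity of the spot and of its local background, and flags of 0 or 1 for spots well above background, saturated or not uniform, which the authors deposited as the software wrote them. The authors also deposited a table of log2 values for the same arrays. The normalization behind that table is not given in the sources used here. Its columns rose with the log2 signal of the same array (r from 0.99955 to 0.99997 over probes) and less closely with that of any other array (highest r 0.992), so its direction and row order are known. The column medians lay between 7.72 and 7.77, so the arrays had been brought to a common level, but the method and the centring constant remain unknown.

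Each array has 15744 spots, of which 536 are control spots and 15208 are probes, 1 spot each. Over all arrays 185 spots marked as outliers were left out, and 0 probes were saturated. Values were log2 of the processed signal minus the log2 of each array's 75th percentile over probes. A probe was kept when it was well above background on at least 3 of the 4 arrays of at least 1 group, which left 13146 probes, 11144 of them well above background on all 16 arrays. The 75th percentile of the signal ran from 921 to 3418 over the arrays, and 80.9% to 87.8% of probes were well above background. The number of arrays limits the precision: the median 95% confidence interval of a fold change reached 0.66 to either side on the log2 scale. That interval comes from the fit without a block, which leaves out the pairing by replicate number described below.

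Groups were compared with limma 3.58.1 in R 4.3.3, in one fit of group means over all 16 arrays, with the two-sided moderated test and Benjamini-Hochberg adjustment over the kept probes within each comparison. A probe was called at an adjusted p below 0.05. The comparisons were each treated group against control and each pair of treated groups, 6 in all, and a moderated F test for any difference among the 4 groups. A probe that no array of a group measured well above background has only a bound there. Its fold is then given as at least the brighter group's mean over the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

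The files name each probe by an identifier and by a contig or sequence (14499 names), without gene symbols. Of these names 0 matched a symbol or accession in the table of RefSeq genes for assembly fPimPro1.hap1.1, so no probe is given a gene name here. The 35 gene lists fixed before the data were examined, and the genes to be reported in every case, could therefore not be tested: 0 lists had a measured member. For probes without a gene name the rule fixed beforehand allows at most 2 identifiers per direction and comparison. These are the called probes with the largest change, and otherwise the probes with the smallest p whose 4 values in each of the groups compared do not overlap. The third called probe of the LIN comparison lies outside that rule and was added after its values were seen.

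The titles number the replicates, and groups share some of the numbers. Whether a number pairs samples was checked apart from the calls: deviations of the arrays from their group means were correlated over probes. All 16 pairs of arrays with the same number in different groups correlated, at r from 0.354 to 0.772, and the highest correlation of each of the 15 arrays with such a partner was with a partner of its number. The numbers therefore pair the samples. The labels do not say what a number marks. Results are given with the number as a fixed block and as a random block (estimated correlation 0.631) where either changes a call or moves a count of a comparison, called or at an unadjusted p below 0.05, by more than 1.5 times.

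The arrays lay on 3 slides, with 7, 2 and 7 arrays, and were scanned on 2 days. Slide 1 was scanned on one day and slides 2 and 3 on the other, so scan day cannot be told apart from slide 1 against the rest. Slides 1 and 3 held all groups, slide 1 with 1 control array and slide 3 with 1 flutamide array. Slide 2 held 1 control and 1 flutamide array. All control arrays lay in row 1 of a slide, all flutamide arrays in row 3, LIN arrays in rows 2 and 4, and DHT arrays in rows 1 and 2. Control arrays thus shared no row with flutamide or LIN arrays. Slide row therefore cannot be told apart from either compound, and it was not tested. The slide was used as a block, and results were also computed within slides. Alternatives chosen before the data were examined were median scaling, quantile normalization, normexp background correction with an offset of 50, the authors' log2 table, other filters on dim probes, blocks for replicate number, slide and scan day, array weights, other variance models, a fit of only the groups compared, and leaving out each array. The files have no mean spot signal, so normexp was run on the median signal and median background. Alternatives added after seeing the data were slide and replicate number together as blocks, centring on spike-in control spots, and slides 1 and 3 alone.

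The fit was tested on simulated data for LIN minus control with 13146 probes, 100 changed by 2-fold and 100 by 4-fold. With independent arrays it recovered 39% of the 2-fold and 70% of the 4-fold changes. With arrays of one number correlated it recovered 39% and 84%, and the random block raised this to 57% and 94%. These shares hold for that many changed probes. With fewer changed probes the adjustment is stricter and recovery lower. The fixed replicate block was not simulated. Figures were drawn with matplotlib 3.10.9.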

Results

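Transcript levels were measured in fathead minnow ovary explants, pieces of ovary kept in culture, after 12 h as controls or with DHT, flutamide or LIN at 1e-06 M, with 4 arrays per group. DHT is the usual abbreviation of dihydrotestosterone, an androgen. Flutamide is a drug that blocks the androgen receptor. LIN is read here as linuron, a urea herbicide that the series title names. That title states an interest in gene networks common to linuron and flutamide in the ovary. The 75th percentile of the signal ranged from 921 to 3418 between arrays. Between 80.9% and 87.8% of the probes on an array were well above background. Arrays correlated over probes at r from 0.936 to 0.968 within a group and from 0.932 to 0.994 between groups. Levels below are log2 values relative to the array's 75th percentile.

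DHT against control asked what an androgen changed in the explants. No probe was called: limma found 0 of 13146 probes, and 269 lay at an unadjusted p below 0.05 (101 higher, 168 lower). Chance alone gives 657.3 with independent arrays. That number leaves out the pairing by replicate number, so 269 cannot be read as below chance. The share lower was 62.5%, against 49.5% with median scaling and 99.5% with centring on spike-in spots. The lowest p belonged to UF_Ppr_AF_117765, a probe for sequence gi_73642462. Its level was -5.96 ± 0.22 (SD, n = 4) with DHT and -4.39 ± 0.65 (SD, n = 4) in control, a difference of -1.57 ± 0.33 (SE) that did not pass (limma adjusted p = 1.00). UF_Ppr_AF_104909, for FJU.11200.C2, had the lowest p among probes with a higher level, at 0.59 ± 0.17 (SE), and did not pass either (limma adjusted p = 1.00). UF_Ppr_AF_115104, for FJU.3635.C6, was not well above background on any DHT array and was well above it on 3 of 4 control arrays, at least 1.56-fold lower with DHT without passing the test. UF_Ppr_AF_116171, for gi_73497819, was not well above background on any control array and was well above it on 3 of 4 DHT arrays, with no fold to give. With the replicate number as a fixed or a random block the count of calls was also 0. The count at an unadjusted p below 0.05 then rose above 657.3, to 912 (454 higher, 458 lower) and 999 (492 higher, 507 lower). Within slide 1 and within slide 3 no probe was called, with 41 higher and 112 lower, and 128 higher and 293 lower, at an unadjusted p below 0.05. The fold changes of the 2 slides correlated at r = -0.06 across probes, which are not independent replicates.

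Flutamide against control asked what an androgen receptor blocker changed. 2 probes were lower and 0 were higher. UF_Ppr_AF_117765 fell by 2.41 ± 0.33 (SE) on the log2 scale, a 5.33-fold decrease, from -4.39 ± 0.65 (SD, n = 4) to -6.81 ± 0.55 (SD, n = 4; limma adjusted p = 0.0394), and 3 of the 4 flutamide arrays were well above background. UF_Ppr_AF_101427, for contig FJU.6392.C3, fell by 1.54 ± 0.22 (SE), a 2.91-fold decrease, from -2.91 ± 0.28 (SD, n = 4) to -4.45 ± 0.17 (SD, n = 4; limma adjusted p = 0.0399). All 4 flutamide values of each probe lay below all 4 control values. These groups also differed in slide row, which cannot be told apart from the compound. On slides 1, 2 and 3 the difference was -1.65, -2.52 and -2.47 for the first probe and -1.71, -1.41 and -1.52 for the second. Slide 1 held 1 control array, slide 2 held 1 array of each group and slide 3 held 1 flutamide array. The sign on each slide was fixed by the lack of overlap between the groups, so it is no separate support. The size depended on the processing: over the alternatives the difference ran from -2.98 to -0.82 for the first and from -2.11 to -0.89 for the second. The first stayed called in 12 of 33 alternatives and the second in 15 of 34. With slide as a block both remained past the threshold (limma adjusted p = 0.0428 and 0.0145). Neither passed with slides 1 and 3 alone and slide as a block, nor with no filter, the trended robust prior or no moderation.

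Among probes with higher levels after flutamide none passed. UF_Ppr_AF_109988, for FJU.728.C8, stood at 3.19 ± 0.12 (SD, n = 4) against 1.94 ± 0.19 (SD, n = 4) in control, a difference of 1.24 ± 0.25 (SE; limma adjusted p = 0.290). UF_Ppr_AF_116171 was well above background on 4 of 4 flutamide arrays and on 0 control arrays, at least 1.33-fold higher (limma adjusted p = 0.290). At an unadjusted p below 0.05 there were 425 higher and 939 lower probes, 68.8% lower. Slide as a fixed block gave 611 higher and 1759 lower there, scan day 582 and 1745, and centring on spike-in spots 10 and 3952. That share was 46.8% with median scaling, 57.2% with normexp and 99.7% with centring on spike-in spots. With the replicate number as a fixed block the majority turned, with 956 higher and 674 lower (41.3% lower), and as a random block there were 935 higher and 1039 lower (52.6% lower). Both calls ended with the replicate number as a fixed block, where 0 probes passed. Their differences were then -2.50 ± 0.37 (SE) and -1.32 ± 0.27 (SE), each with a limma adjusted p of 0.244. That block leaves fewer residual degrees of freedom. Flutamide replicate 2, whose number no other array has, then adds nothing to the comparison. With the number as a random block 14 probes passed, 4 higher and 10 lower, and both probes were among them. Leaving out any of 11 of the 16 arrays gave 0 calls. Within slide 1, which held 1 control array, 0 probes were called (249 higher and 732 lower at an unadjusted p below 0.05), and within slide 3, which held 1 flutamide array, 10 were.

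**Figure D1:**
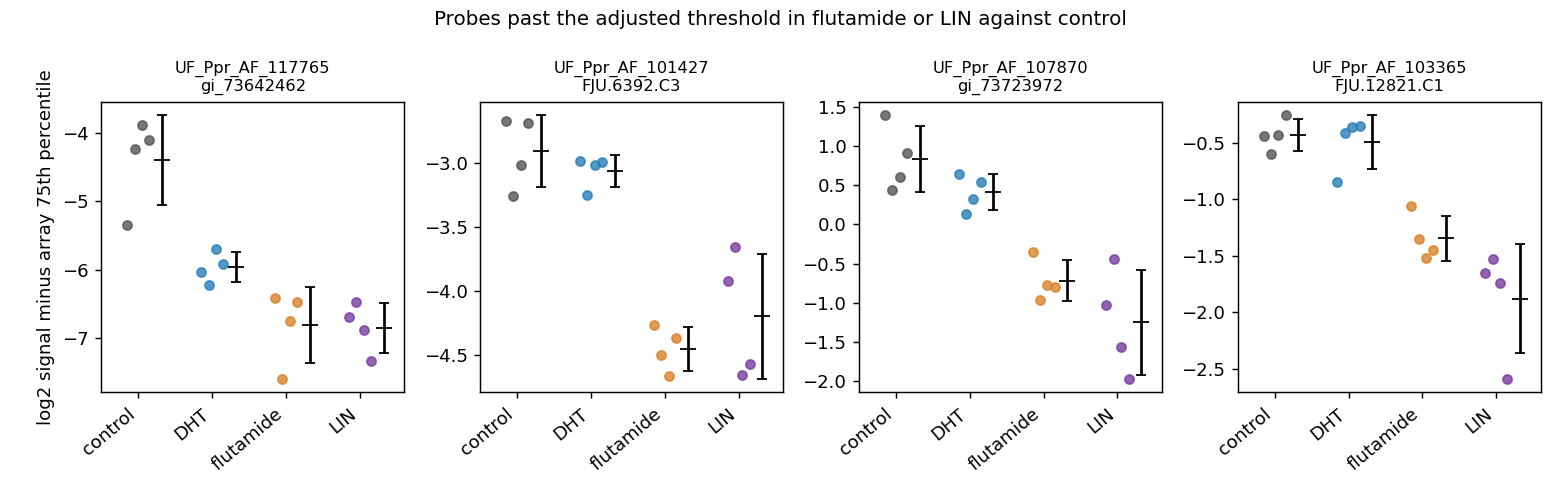
Levels of the 4 called probes on every array, as log2 signal minus the array's 75th percentile, by group; points are arrays and bars are the mean ± SD of 4 arrays. The mean of UF_Ppr_AF_117765 lies below control in all 3 treated groups, without passing the test for DHT, and the DHT means of UF_Ppr_AF_101427, UF_Ppr_AF_107870 and UF_Ppr_AF_103365 differ from control by -0.15, -0.43 and -0.06, also without passing.

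LIN against control asked what the herbicide changed. 3 probes were lower and 0 were higher. UF_Ppr_AF_117765 fell by 2.45 ± 0.33 (SE), a 5.47-fold decrease, to -6.84 ± 0.37 (SD, n = 4; limma adjusted p = 0.0331). UF_Ppr_AF_107870, for gi_73723972, fell by 2.09 ± 0.30 (SE), a 4.26-fold decrease, from 0.84 ± 0.42 (SD, n = 4) to -1.25 ± 0.67 (SD, n = 4; limma adjusted p = 0.0365). UF_Ppr_AF_103365, for FJU.12821.C1, was the third and fell by 1.45 ± 0.22 (SE), a 2.73-fold decrease, from -0.43 ± 0.14 (SD, n = 4) to -1.88 ± 0.48 (SD, n = 4; limma adjusted p = 0.0454). All 4 LIN values of each lay below all 4 control values. LIN and control arrays shared no slide row, so row cannot be told apart from the compound. Within slide 1, with 1 control array, and slide 3 the differences were -1.23 and -3.11 for the first, -2.13 and -2.53 for the second and -1.16 and -1.82 for the third. Their sign was fixed by the lack of overlap between the groups, so it is no separate support. Over the alternatives the differences ran from -2.77 to -0.76 for the first, -2.36 to -1.81 for the second and -1.79 to -1.21 for the third. The 3 probes stayed called in 13 of 33, 15 of 34 and 12 of 34 alternatives. With slide as a block the 3 probes stayed past the threshold (limma adjusted p = 0.0402, 0.0379 and 0.0490).

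Higher levels after LIN did not pass. UF_Ppr_AF_101912, for FJU.9244.C2, was at -3.62 ± 0.92 (SD, n = 4) against -7.35 ± 1.44 (SD, n = 4) in control, where 2 of 4 arrays were well above background (limma adjusted p = 0.187). UF_Ppr_AF_103609, for FJU.12675.C2, differed by 1.27 ± 0.25 (SE; limma adjusted p = 0.195). At an unadjusted p below 0.05 there were 335 higher and 1033 lower probes, 75.5% lower. That share was 50.3% with median scaling, 57.6% with quantile normalization, 55.6% with normexp, 60.8% in the authors' log2 table and 78.6% with centring on spike-in spots. The fixed replicate block gave 854 higher and 1174 lower (57.9% lower), slide as a fixed block 371 and 2054, scan day 386 and 1995, and centring on spike-in spots 183 and 674. With the replicate number as a fixed block 0 probes passed. The differences of the 3 probes were then -2.55 ± 0.33, -1.90 ± 0.31 and -1.52 ± 0.23 (SE), with limma adjusted p of 0.0843, 0.136 and 0.103. These differences and SE were near those without a block, and the block leaves fewer residual degrees of freedom. With the number as a random block 147 passed, 63 higher and 84 lower, and all 3 probes were among them. The random block gave 2384 probes at an unadjusted p below 0.05, 797 higher and 1587 lower. Leaving out any of 12 of the 16 arrays gave 0 calls, and leaving out LIN replicate 4 gave 81, 18 higher and 63 lower. Within slide 1 and within slide 3 no probe was called, with 126 higher and 228 lower, and 421 higher and 2594 lower, at an unadjusted p below 0.05.

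Flutamide and linuron are non-steroidal compounds with a substituted benzene ring, flutamide an anilide and linuron a phenylurea, and were given at the same concentration and time. Compared with each other, limma called 0 of 13146 probes, and 130 lay at an unadjusted p below 0.05 (64 higher, 66 lower after flutamide). The share lower was 50.8%, and 99.6% with centring on spike-in spots. With the replicate number as a fixed block 996 lay there (753 higher, 243 lower) and as a random block 817 (581 higher, 236 lower), again with 0 calls. The median interval of the difference reached 0.66 to either side on the log2 scale in the fit without a block. It and the intervals that follow leave out the pairing by number. For UF_Ppr_AF_117765 flutamide minus LIN was 0.04 (95% interval -0.66 to 0.74). For UF_Ppr_AF_101427 it was -0.25 (-0.73 to 0.22), and for UF_Ppr_AF_107870 it was 0.53 (-0.11 to 1.17). For UF_Ppr_AF_103365 it was 0.53 (0.07 to 1.00), which did not pass the adjustment (limma adjusted p = 1.00). The lowest p belonged to UF_Ppr_AF_112809, for gi_73719313, at -4.27 ± 0.20 (SD, n = 4) after flutamide and -5.01 ± 0.18 (SD, n = 4) after LIN, and it did not pass. UF_Ppr_AF_104057, for FJU.4228.C1, was at -5.12 ± 0.72 (SD, n = 4) after flutamide and -3.09 ± 0.82 (SD, n = 4) after LIN, and did not pass. Within slide 1 no probe was called (70 higher and 194 lower at an unadjusted p below 0.05), and within slide 3, with 1 flutamide array, 15 were. The fold changes of the 2 slides correlated at r = -0.17 across probes.

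UF_Ppr_AF_117765 was the 1 probe called for both compounds in the fit without a block. With the replicate number as a random block 9 lower probes were called for both, and as a fixed block 0 probes were called for either. In the fit without a block, at an unadjusted p below 0.05, flutamide and LIN shared 538 lower and 196 higher probes, and 0 probes went opposite ways. Independent lists of those lengths would share 73.8 and 10.8, a number that leaves out the shared controls. Simulated unchanged groups with shared controls shared 74.1 lower and 73.1 higher probes on average with independent arrays, against 8.20 and 8.14 for independent lists of their lengths, and 17.2 and 18.4, against 0.738 and 0.785, with arrays of one number correlated. DHT and flutamide shared 112 lower and 30 higher probes (12.0 and 3.27 for independent lists), and simulated unchanged groups in their place 72.7 and 73.8 with independent arrays (8.26 and 8.23) and 13.04 and 12.84 with arrays of one number correlated (0.702 and 0.727). DHT and LIN shared 85 and 29 (13.2 and 2.57), and the simulated groups 73.4 and 74.0 (8.21 and 8.16) and 9.96 and 10.5 (0.372 and 0.385). With independent arrays, sharing the controls alone gave simulated overlaps several times those of independent lists. With arrays of one number correlated, the simulated groups shared numbers as well as controls. With the replicate number as a random block, flutamide and LIN shared 614 lower and 441 higher probes, and 3 went opposite ways. DHT and flutamide then shared 277 and 236 (4 opposite), and DHT and LIN 234 and 210 (6 opposite). Without a block, fold changes of flutamide and LIN correlated at r = 0.784 across 13146 probes (jackknife SE over arrays 0.185; Spearman 0.789), which are not independent replicates. Both use the same control arrays: simulated unchanged groups against shared controls gave r = 0.50 with independent arrays and 0.568 with arrays of one number correlated. The covariance was 0.218, against 0.121 and 0.0829 in those simulations, a difference of 0.0972 and 0.136. With the controls split into 2 and 2, r was 0.206 on average over 6 ways of splitting them (0.0689 to 0.296). DHT and flutamide correlated at r = 0.624, with a covariance 0.0181 and 0.0759 above the simulated values, and at 0.034 with split controls. DHT and LIN correlated at r = 0.581, with a covariance 0.00556 and 0.0627 above, and at -0.00383 with split controls. The fold changes with split controls still shared replicate numbers. Where they shared no array and no number, the median r was 0.244 for flutamide and LIN, 0.281 for DHT and flutamide and 0.203 for DHT and LIN. The values with split controls therefore do not set flutamide and LIN apart.

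Flutamide against DHT and LIN against DHT set the blocker and the herbicide beside the androgen. limma called 0 probes in each, although within slide 3 alone, with 1 flutamide array, 6 passed for flutamide against DHT. At an unadjusted p below 0.05 there were 158 higher and 510 lower probes for flutamide and 115 higher and 791 lower for LIN. The share lower was 76.3% and 87.3%, against 64.0% and 74.3% with median scaling, 67.2% and 73.2% with quantile normalization, and 95.8% and 25.1% with centring on spike-in spots. For LIN it was 73.0% with normexp and 74.1% in the authors' log2 values. For flutamide the majority turned with the fixed replicate block, with 337 higher and 248 lower (42.4% lower), and the random block gave 306 higher and 506 lower. UF_Ppr_AF_101427 differed by -1.39 ± 0.22 (SE) for flutamide against DHT (limma adjusted p = 0.250). UF_Ppr_AF_103365 differed by -1.39 ± 0.22 (SE) for LIN against DHT (limma adjusted p = 0.145). UF_Ppr_AF_117171, for gi_72763384, had a difference of -1.01 ± 0.16 (SE) for LIN against DHT (limma adjusted p = 0.145). UF_Ppr_AF_117784, for gi_72424021, stood 1.49 ± 0.33 (SE) above DHT with flutamide and 1.32 ± 0.33 (SE) above it with LIN, without passing. With the replicate number as a random block 46 probes passed for LIN against DHT, 1 higher and 45 lower, and with it as a fixed block 0 passed. That comparison then had, at an unadjusted p below 0.05, 1676 probes (309 higher, 1367 lower) and 1362 (336 higher, 1026 lower). The moderated F test over the 4 groups called 2 probes, UF_Ppr_AF_117765 and UF_Ppr_AF_101427 (limma adjusted p = 0.0430 for each; 913 probes at an unadjusted p below 0.05), and called 0 with the fixed and 59 with the random replicate block.

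Lower levels after flutamide and LIN gathered among dim probes. In the dimmest of 5 equal groups of probes the median log2 fold change was -0.27 for flutamide, -0.34 for LIN and -0.03 for DHT. In the brightest it was 0.06, 0.01 and 0.00. An index per array, the median deviation of the 3 dimmer groups of probes minus that of the 2 brighter ones, averaged 0.15 ± 0.21 (SD, n = 4) in control, -0.12 ± 0.15 (SD, n = 4) with flutamide and -0.13 ± 0.36 (SD, n = 4) with LIN. Neither difference passed an exact two-sided permutation test (p = 0.0857 and 0.286; Benjamini-Hochberg 0.257 and 0.429 over 3 comparisons; smallest possible p 0.0286). That test leaves out the pairing by number. With the number as a fixed block the differences were -0.10 ± 0.16 (SE) for flutamide and -0.18 ± 0.14 (SE) for LIN. After quantile normalization, without a block, both differences were -0.06.

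**Figure D2:**
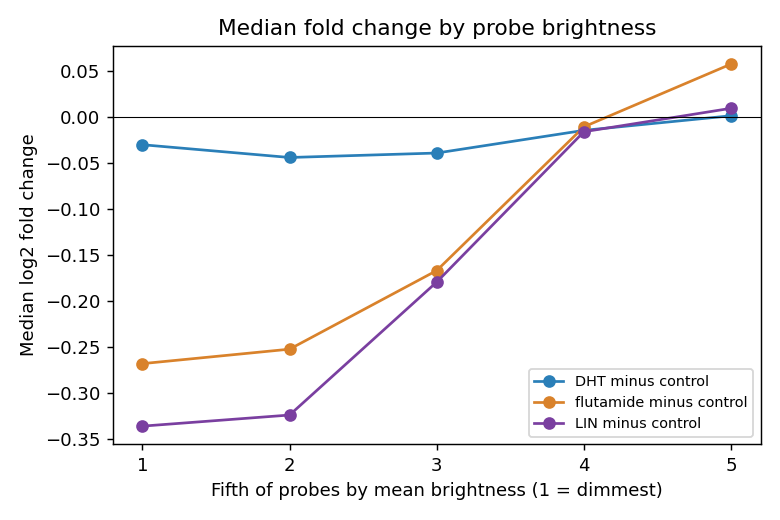
Median log2 fold change against control in 5 groups of probes ordered by mean brightness, for DHT, flutamide and LIN. The flutamide and LIN lines run from -0.27 and -0.34 in the dimmest group to 0.06 and 0.01 in the brightest, and the DHT line stays between -0.04 and 0.00.

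Arrays that shared a replicate number deviated from their group means together. The correlation of deviations averaged 0.590 over 16 such pairs, -0.07 over 27 pairs with different numbers on one slide and -0.14 over 53 pairs with different numbers on different slides. Taken singly, the 6 numbers covered 71.0% of the variance summed over probes, the 4 groups 17.9% and the 3 slides 20.8%. A factor with more levels covers more variance by chance alone. No chance share was computed, so these shares do not measure the size of an effect.

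**Figure D3:**
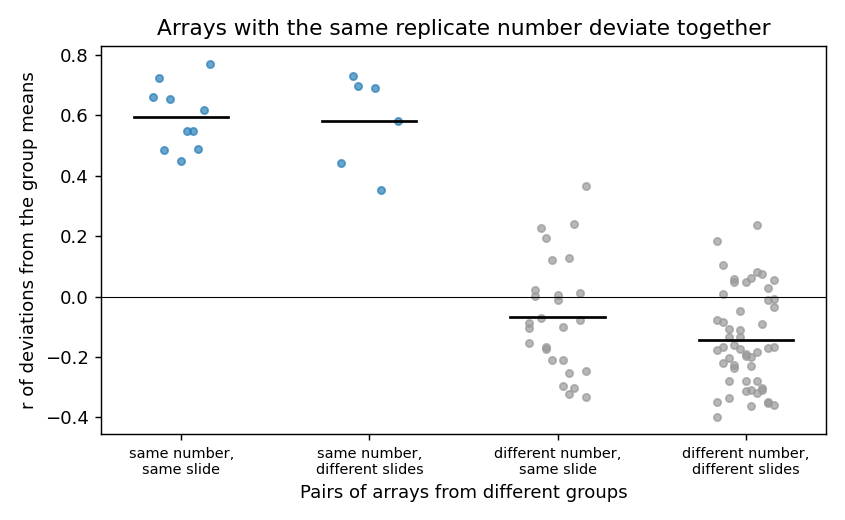
Correlation over probes of the deviations from the group means, for pairs of arrays of different groups; each point is a pair and each line a mean. Pairs with the same replicate number lie between 0.354 and 0.772, on the same slide or on different slides, and pairs with different numbers lie between -0.40 and 0.367.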

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

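In 88 groups of 4 values, for the named probes and 4 measures of array quality, 1 array stood far from the other 3 in 8 groups. Chance alone gives about 4.4. No explanation was tested for these values.

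UF_Ppr_AF_109988 was at 1.66 on control replicate 6, where the other controls lay between 2.03 and 2.04. UF_Ppr_AF_101427, called for flutamide, was at -3.25 on DHT replicate 4, with the other DHT arrays between -3.02 and -2.99. UF_Ppr_AF_103365, called for LIN, was at -0.85 on DHT replicate 1, with the others between -0.41 and -0.35. UF_Ppr_AF_115104 was at -9.54 on flutamide replicate 5 and between -8.20 and -8.04 on the rest, not well above background on any of the 4. UF_Ppr_AF_104057 was at -4.04 on flutamide replicate 5 and between -5.57 and -5.43 on the rest. UF_Ppr_AF_104909 was at -2.42 on LIN replicate 6, with the others between -2.13 and -2.08. UF_Ppr_AF_116171 was at -8.24 on LIN replicate 6, with the others between -7.54 and -7.45. The spike-in level over the 75th percentile was 2.48 on DHT replicate 4 and between 1.87 and 1.93 on the other DHT arrays.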

How the results depend on the processing

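All 841 values of named probes, picked by p or change, kept direction under the alternatives. In 721 the side of the threshold was kept, mostly uncalled. Each call held in 12 to 15 of 33 or 34. Causes were not tested, but leaving out arrays or groups leaves fewer samples. Gene lists had no measured member, so none was rerun. For DHT and for flutamide against LIN every alternative at the adjusted threshold gave 0 calls, including each array left out (0 to 0), though within slide 3 alone flutamide against LIN had 15 (and flutamide against DHT 6).

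For flutamide against control, 2 calls became 1 with normexp, quantile normalization, the authors' log2 table or probes well above background on all 16 arrays. They became 0 with no filter, the trended robust prior, no moderation, or only the groups compared, and 4 with slide as a fixed block. For LIN against control, 3 calls became 10 with the authors' table (3 higher, 7 lower), 6 with slide as a fixed or random block, and 0 with no moderation or only the groups compared. Flutamide against DHT had 2 calls with normexp and 1 with quantile normalization, median scaling, the authors' table or array weights. LIN against DHT had 3 with normexp, 6 with quantile normalization and 1 with array weights. The F test's 2 calls became 5 with normexp or quantile normalization, 1 with the authors' table or probes well above background on all 16 arrays, and 0 with no filter or no moderation. They became 4 with slide (fixed or random), scan day, array weights, the trended robust prior or an adjusted p below 0.10.

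The replicate number changed the calls of flutamide and LIN against control, LIN against DHT and the F test, and no other count of calls. Counts at an unadjusted p below 0.05 moved by more than 1.5 times for DHT against control (912 with the fixed and 999 with the random block), LIN against control (2384, random), flutamide against LIN (996 and 817) and LIN against DHT (1362 and 1676). Other choices that moved them so, for DHT, were normexp (573), quantile normalization (422), the authors' table (413), scan day (483), array weights (515) and only the groups compared (412). For flutamide against control they were slide (2370) and scan day (2327), for LIN slide (2425), scan day (2381) and only the groups compared (894), and for flutamide against LIN quantile normalization (228), the authors' table (234), slide (247) and only the groups compared (82). For calls, with the fixed replicate block these were 0, 0, 0 and 0, and with the random replicate block 14, 147, 46 and 59. Chosen after seeing the data, slide and replicate block together gave 0 for flutamide, LIN and the F test. Spike-in centring gave 111 (all lower), 0 and 1. Slides 1 and 3 alone gave 0 for flutamide, 1 for LIN against DHT and 1 for the F test. At an unadjusted p below 0.05 spike-in centring gave 808 for DHT, 3962 for flutamide, 857 for LIN, 1026 for flutamide against LIN and 466 for LIN against DHT. Slides 1 and 3 alone gave 505, 2765, 2742 and 320 for the first 4 of these and 1004 for flutamide against DHT, and slide and replicate block together 657 for DHT, 1034 for flutamide against LIN and 1668 for LIN against DHT. Spike-in centring moved the median log2 fold change to -0.46 for DHT, -0.65 for flutamide and -0.13 for LIN, from -0.02, -0.09 and -0.11. Median scaling moved it to 0.02, 0.07 and 0.09.

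At an unadjusted p below 0.05 the counts were 269, 1364 and 1368 for DHT, flutamide and LIN against control, 130 for flutamide against LIN, 668 and 906 for flutamide and LIN against DHT, and 913 for the F test. With each array left out they ran from 138 (without DHT replicate 4) to 406 (DHT replicate 1), from 846 (flutamide replicate 5) to 1800 (control replicate 3) and from 802 (LIN replicate 6) to 2498 (LIN replicate 4) against control. They ran from 109 (LIN replicate 6) to 325 (LIN replicate 5) for flutamide against LIN, from 421 (flutamide replicate 2) to 812 (LIN replicate 4) for flutamide against DHT and from 443 (LIN replicate 6) to 1708 (LIN replicate 4) for LIN against DHT. Other moves over 1.5 times were 870 and 837 for LIN against control without control replicate 1 or LIN replicate 5, and 247 and 244 for flutamide against LIN without LIN replicate 4 or flutamide replicate 5. With each array left out, calls ran from 0 to 3 for flutamide, 0 to 81 for LIN and 0 to 6 for the F test, and 0 to 0 for flutamide and LIN against DHT. Flutamide had 3 without LIN replicate 3, 2 without LIN replicate 4, 5 or 6, 1 without control replicate 1 and 0 without any other array. LIN had 81 without LIN replicate 4, 3 without DHT replicate 1, 1 without control replicate 1 or flutamide replicate 5 and 0 without any other array. The F test had 6 without LIN replicate 4, 1 without control replicate 1 and 0 otherwise. Correlations of fold changes with each control left out ran from 0.804 to 0.834 (flutamide and LIN), 0.665 to 0.715 (DHT and flutamide) and 0.624 to 0.673 (DHT and LIN). With the controls split into 2 and 2 they were 0.206, 0.034 and -0.00383, the last of opposite sign. The split ones still shared replicate numbers. The signal over background limits dim probes: 13146 of 15208 were kept.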

Other observations

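Tests chosen only after the result was seen were both of slide for the replicate numbers, those of brightness as a covariate or apart from the number, and the counts of other splits. The contigs FJU.6392.C2 and FJU.6392.C5, singled out after their values were seen, share the number in their name with the called FJU.6392.C3. Their fold changes were -1.24 and -1.16 for flutamide, -1.67 and -0.89 for LIN, and -0.12 and -0.02 for DHT, and none passed the threshold. What the shared number means is not given in the sources used here. Over 1973 pairs of probes whose contig names share it, deviations from the group means correlated at a median r of 0.172, and at 0.061 when the same probes were paired at random.

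Of the 710 probes with AM in their name, 709 share a sequence name with a probe with AF. Among 329 such pairs with both probes kept, the fold changes correlated at r = 0.067 for DHT, 0.051 for flutamide and -0.039 for LIN across pairs. 53.5% of the AM spots and 81.0% of their AF partners were well above background.

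Same-number arrays deviated together. The position in a slide column does not account for all of it: pairs of one number in different columns correlated higher by 0.682 on average than pairs of different numbers in one column. The latter reached 0.367, above the lowest of the former (0.354). The 6 pairs of one number in different columns were also the 6 on different slides, so column and slide were not tested apart. Slide cannot be the whole cause either: among pairs on different slides, those of one number lay higher by 0.726 on average than those of different numbers, with every one of them (lowest 0.354) above the highest of the others (0.237). Pairs of one number on different slides also lay higher by 0.649 on average than pairs of different numbers on one slide, though 1 of the latter reached 0.367. A shared fish, tissue pool or day of incubation may lie behind a number, and the labels do not say.

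Dim probes lay lower relative to brighter ones after flutamide and LIN, without passing the permutation test. Within groups the index fell with array brightness (r = -0.77; Spearman -0.74; r = -0.74 without the 2 arrays of most extreme brightness, -0.97 in slide 1, -0.70 in slide 3), which met the bound set beforehand for a technical cause. Same-number arrays are not independent, however, and with the number also removed r was -0.425, between the bounds of 0.3 and 0.5, with 6 residual degrees of freedom, so brightness cannot be told apart from what arrays of one number share. The mean log2 75th percentile was 10.81 with flutamide, 11.05 with LIN and 11.10 in control. The treated groups were thus dimmer on average, while the index fell with brightness, so this difference runs against their lower index. With brightness as a covariate the difference of the index was -0.35 ± 0.11 (SE) for flutamide and -0.29 ± 0.11 (SE) for LIN, from -0.27 and -0.28 without it. With the replicate block as well it was -0.53 ± 0.40 (SE) and -0.36 ± 0.21 (SE), from -0.10 and -0.18 with the block alone. Adjustment for brightness shrank neither difference. With the block both stayed within 2 SE, so the bound for excluding a brightness difference between the groups was not met there. The spike-in level stays open as a cause (r = 0.383, Spearman 0.418, r = 0.482 without the 2 most extreme arrays, 0.022 in slide 1, 0.714 in slide 3, and 0.306 with the number removed). With the replicate block alone the difference kept 0.387 of its size for flutamide (-0.10 ± 0.16, SE) and 0.637 for LIN (-0.18 ± 0.14, SE). The flutamide share met the bound set beforehand for unequal numbers as a cause, but its SE exceeds the difference. The LIN difference lay within its spread too, so unequal numbers stay open for both compounds. An effect of the compounds remains an untested hypothesis.

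Fold changes of flutamide and LIN went together also where they shared no array and no replicate number: the median r over 11 such splits was 0.244 (0.0578 to 0.405, above 0 in all 11), which argues against shared controls and numbers as the whole cause. DHT with flutamide gave a median of 0.281 over 12 splits and DHT with LIN 0.203 over 12, and flutamide with itself gave 0.255 over 5 and LIN with itself 0.354 over 6. DHT with itself gave 0.247 over 6. These values do not set flutamide and LIN apart from the pairs with DHT: a difference of the control arrays from all treated arrays may lie behind them, and a response of flutamide and LIN alone was not shown. Control arrays shared no slide row with flutamide or LIN arrays, and row was not tested. The splits overlap and their slides were not separated.

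Other splits of the 8 arrays of a comparison into 4 and 4 (35 splits with the real one) were counted at an unadjusted p below 0.05. For DHT against control 19 splits gave at least the real 269 (highest other 1452), for flutamide 3 gave at least 1364 (highest other 1840), and for LIN 5 gave at least 1368 (highest other 3532). For flutamide against LIN 33 gave at least 130 (highest other 2909), for flutamide against DHT 11 gave at least 668 (highest other 1210), and for LIN against DHT 9 gave at least 906 (highest other 2880), so chance cannot be excluded for any of these counts by splits that ignore the pairing. For adjusted calls, only the real split of flutamide reached 2 (1 of 35, highest other 0), but these splits ignore the pairing by number. The 12 that part as many pairs are too few for a share under 0.05. The fixed replicate block, which leaves fewer residual degrees of freedom, left 0 calls. This count alone therefore does not exclude chance. For LIN 2 splits reached 3, the other with 939, so chance cannot be excluded. For the F test 7 of 100 groupings reached the real 2 calls (highest other 14), and 31 of 100 reached 913 at an unadjusted p below 0.05 (highest other 2223). Chance cannot be excluded for either.

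Splits with several times the real count point to a structure of the samples. The one with 939 calls exchanges LIN replicate 4 and control replicate 3, which puts both arrays of number 3 on one side and both of number 4 on the other. Splits that follow the slide gave 2880 for LIN against DHT, 1902 for flutamide against LIN and 676 for DHT against control, above the real counts, and 939 for LIN against control and 440 for flutamide against DHT, below the real 1368 and 668. Those of LIN against DHT, flutamide against LIN and flutamide against DHT also follow the scan day. The split of LIN against DHT parts no pair of numbers, so slide, scan day and number cannot be told apart there. With slide as a block the real counts of the 5 comparisons were 1216, 247, 378, 2425 and 635, and that of flutamide against control, where no split follows the slide, was 2370. The real split parts every shared pair of numbers. Among splits that part as many pairs (12 for flutamide against control or DHT, 8 for the others) no other reached an adjusted call, and the splits are too few for a share under 0.05. Among these, at an unadjusted p below 0.05, the real count was the highest for DHT against control (269, highest other 192), flutamide against DHT (668, highest other 345) and LIN against DHT (906, highest other 771). It was not for LIN (1368, highest other 1573) and flutamide (1364, highest other 1537) against control or flutamide against LIN (130, highest other 804).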
